A study of Mus musculus with 3 samples.

How the data were processed

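The gene expression matrix holds UMI counts per gene and cell barcode that the authors made with Cell Ranger 6.0.1 against mm10, per the file headers and labels, and the gene annotation is not stated there. The tag matrix holds UMI counts per antibody tag and barcode as deposited, with the counting tool not stated. The receptor table holds UMI and read counts per assembled contig as deposited, in the format of Cell Ranger. The remaining deposited columns have the unit other and hold barcodes, gene names, tag names, contig annotation and the sheet that joins hashtag pairs to replicate number, tissue and genotype, per the file headers. No normalization had been applied to the counts per the file headers. The gene table includes no entry for a reporter or the transgene, so Nrp1 counts cannot be split into endogenous and added transcripts.

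Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs, which left 6386 of 9505 barcodes, and 4 barcodes were absent from the tag matrix. A sample was called when both hashtags of a pair were at least 10 UMIs, more than 3 times the background of that tag, and at least 3 times the next tag of its set, which gave 3908 cells. The first hashtag was not called in 1994 cells, the second in 2110 and neither in 1626, and uncalled cells had a median of 1440 UMIs and 799.5 genes. Background medians of the tags were 5 to 17 UMIs. Doublets between samples were removed by this rule and doublets within a sample remain. The clustering used 2000 variable genes, 20 principal components, 15 neighbors and Leiden resolution 1 in scanpy 1.11.5 with igraph 0.11.9 and scikit-learn 1.9.0. Nrp1, heat-shock, immediate early, exocrine, ribosomal, mitochondrial, receptor and immunoglobulin genes, Xist, Malat1 and Gm gene models were taken out of these genes. The Treg and Tconv markers were then added to them. Clusters were Treg-like when at least 50% of cells had a Foxp3 UMI and Tconv-like when at most 15% did, with at least 3 markers of the class detected, unless markers of another cell type prevailed. Clusters in neither class, among them the cycling and interferon-response clusters, were left out of both classes in the main setting. Tests of cell cycle and interferon genes therefore miss those cells. The clustering settings, the class thresholds and the definition of hashtag background were chosen after the data were examined.

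Counts were summed per mouse, tissue and class, and each sum is a library. Genes were tested with edgeR 4.0.16 by its quasi-likelihood method on limma 3.58.1 and R 4.3.3, with an adjusted p (Benjamini-Hochberg) under 0.05 as the threshold, and DESeq2 1.42.0 served as the second tool. The genotypes were compared between mice and the tissues between the libraries of the groups, with the mouse as a block only as an alternative. The pairing of islet and ndLN libraries rests on the replicate number in the hashtag sheet. The expression values do not show it, since correlations of the deviations ran from -0.0571 to 0.0398 and the own partner was the best in 2 of 12. Gene lists were tested with camera at its preset correlation of 0.01 and with an estimated correlation, and with fry. Of 26 lists fixed before the data were examined (342 genes), 19 had enough measured genes for a test in at least 1 comparison. Those were Treg core, Treg effector, quiescence, semaphorin and plexin, Th1, Th17 and Tfh, type I interferon, cell cycle, T cell receptor signalling, NF-kB, glycolysis, oxidative phosphorylation, chemokine receptors, inhibitory receptors, IL-2 and STAT5, apoptosis, immediate early stress, heat shock and exocrine. The lists of CD8, gamma delta, NK, B, myeloid, beta cell and erythroid genes served to name clusters and to measure ambient RNA.

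Values per mouse were compared by exact two-sided permutation of 924 regroupings between genotypes, or 64 sign flips of pairs between tissues, in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. The smallest possible p is 0.00216 for 6 against 6, 0.03125 for 6 pairs and 0.0625 for 5 pairs. Shares of cells with a UMI were repeated after thinning cells to 2000 UMIs with a fixed seed, and cells with fewer UMIs were left out. Clonotypes are cells with the same nucleotide CDR3 of the beta chain and the alpha chain, and groups were drawn to equal size 1000 times. Shuffled labels gave the sharing to be seen if clones were mixed at random over both groups, as a description. Sharing between the genotypes, which are different mice, is the background for chance or doublets. A fold change against a group at 0 is given only where the other group holds at least 3 counts. The steps were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold, and 7 false calls were seen in the islet design and 9 in the ndLN design.

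The genes to name were set before the data were examined. They are the 12 highest and 12 lowest log2 fold changes among genes called and with the same sign in every pair (between genotypes a pair shares only a replicate number), without ribosomal, mitochondrial, receptor-segment, sex-linked and unnamed genes, and up to 4 genes of each list with the largest change. Nrp1, Foxp3 and Sema4a were among those added to each comparison, and Sema4a was too low for a test in Treg. The ranking left out 28 genes in the wild type tissue comparison, 46 in the Nrp1 allele tissue comparison, 1 in ndLN Treg, and 40, 77, 69 and 87 in the Treg against Tconv comparisons. Where several genes of the rule tell of the same group, only some are named. Ccl4, Gm26740 and Trbv13-3 fall outside the rule and were chosen after their values were seen.

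Alternatives set before the data were examined were a cell filter of 1000 genes and 5% mitochondrial UMIs, a hashtag ratio of 10, DESeq2 and its size factors, scaling without ribosomal, mitochondrial and receptor genes, no gene filter beyond 1 UMI, a filter at 100 CPM, the mean of per-cell CPM, Treg with and Tconv without a Foxp3 UMI, leaving out cycling cells (with an Mki67 or Top2a UMI) or cells with at least 3 UMIs of another cell type, the mouse as a block, thinning, Leiden resolutions 0.6 and 1.5 for shares, the beta chain alone, and the deposited clonotype number. Alternatives chosen after the data were examined were Treg as cells with a Foxp3 UMI in any T cell cluster, the classes at the other resolutions, the interferon-response cluster counted as Tconv, libraries of at least 10 cells, leaving out mice 1 and 12 for their pancreatic enzyme RNA, those for Treg against Tconv and for the difference of the differences, and all those for the surface tag and the heat-shock and immediate early UMIs. Pseudocounts and leaving out each replicate in turn were not applied, since both are for designs with fewer replicates. The unmapped tag and the barcodes without a called sample were left out, because neither can be given to a mouse.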

Results

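Messenger RNA, hashtags, an antibody tag against surface Nrp1 with its isotype control, and T cell receptor contigs were read from single T cells of 12 female NOD mice aged 6 weeks. Mice 1 to 6 carried the Foxp3 Cre-GFP allele alone (wild type) and mice 7 to 12 also carried a Cre-dependent Nrp1 transgene at Rosa26 (Nrp1 allele), each sampled in the islets and in a non-draining lymph node (ndLN). Regulatory T cells (Treg) and conventional T cells (Tconv) were loaded at a goal of 50:50, so the ratio of the classes is partly set by the sort. The matrix held 22663310 UMIs. The quality filter kept 6386 barcodes, and 3908 of these carried both hashtags of 1 sample, with a median of 3114.5 UMIs and 1426 genes per called cell. The islets gave 486 wild type cells (27 to 123 per mouse, 128652 to 479021 UMIs) and 834 Nrp1 allele cells (22 to 296 per mouse, 76072 to 1234478 UMIs). The ndLN gave 1245 wild type cells (183 to 246, 602279 to 1023685 UMIs) and 1343 Nrp1 allele cells (197 to 252, 662913 to 827486 UMIs). Each group held 6 mice, and the groups were compared with the mouse as the unit.

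The cells formed 16 clusters, of which 4 were Treg-like by their share of cells with a Foxp3 UMI and 5 were Tconv-like. An Il10, Nfil3, Ctla4, Areg and Tigit cluster held most islet Treg (22.0% of wild type and 17.5% of Nrp1 allele islet cells, but 0.321% and 0.670% of ndLN cells). An Il2ra, Socs2 and Lta cluster (18.2% and 17.9% of ndLN cells) and a Gpr83 and Izumo1r cluster (11.1% and 12.6%) held most ndLN Treg. An S100a4, Itgae and Ccr6 cluster was present in both tissues (8.02% and 6.83% in the islets, 4.74% and 4.62% in the ndLN). Islet Tconv sat mainly in a Ccl5, Cxcr6, Tbx21 and Ifng cluster (17.9% in each genotype), a Vps37b and Plaur cluster (11.3% and 12.9%) and an Xcl1, Ccl4 and Il21 cluster (14.2% and 8.87%). Most ndLN Tconv sat in the Dapl1, Igfbp4 and Lef1 clusters (24.4% and 21.3% in the larger). Clusters outside both classes (interferon-response, cycling, CD8, myeloid, exocrine, B and unnamed cells) held 10.7% of wild type and 14.3% of Nrp1 allele islet cells and 19.2% and 25.8% of ndLN cells. Treg-like cells numbered 177 and 255 in the islets (8 to 45 and 5 to 101 per mouse, 33315 to 187266 and 17651 to 370432 UMIs per library), for wild type and Nrp1 allele in that order. They numbered 428 and 480 in the ndLN (27 to 98 and 64 to 96 per mouse, 133771 to 379067 and 212016 to 345141 UMIs). Tconv-like cells numbered 257, 460, 578 and 516 in islet wild type, islet Nrp1 allele, ndLN wild type and ndLN Nrp1 allele. Confidence intervals and detection floors cover counting error only, and intervals of shares are Clopper-Pearson.

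The first comparison asked which genes separate islet Treg from ndLN Treg of the same wild type mice. Islet Treg carried the effector program of tissue Treg. The cytokine Il10 (log2 fold change 6.32, 99.9 ± 77.4 (SD, n = 6) vs 0.438 ± 1.07 (SD, n = 6) CPM, UMIs scaled to a common library total) and the growth factor Areg (4.31, 193 ± 105 vs 8.81 ± 3.91) rose in the islets in 6 of 6 mice. So did the inhibitory receptors Tigit (2.81, 396 ± 104 vs 62.4 ± 26.9), Ctla4 (2.29, 1653 ± 749 vs 320 ± 69.4) and Lag3 (2.60) and the transcription factor Nfil3 (3.83). The Th1-type genes Ccl5 (5.13, 304 ± 227 vs 11.4 ± 14.1), Ifng (4.31, 82.2 ± 50.5 vs 2.99 ± 4.11, 5 of 6 mice) and Cxcr3 (2.47, 169 ± 40.2 vs 36.8 ± 36.4) rose as well. In both genotypes Ifng was under the gene filter at a hashtag ratio of 10 and when Treg were only cells with a Foxp3 UMI. Further genes that rose were Cxcr4 (3.68), Cxcl10 (4.46), Ramp3 (4.90), Gem (4.46), Cdkn1a (3.81) and Klf6 (2.80). Antigen-receptor response genes followed, with Nr4a1 at 2.45 (717 ± 141 vs 143 ± 85.1), Nr4a2 at 3.78, Fosl2 at 5.24 (187 ± 95.7 vs 3.87 ± 4.24) and the NF-kB inhibitor Tnfaip3 at 2.33 (987 ± 132 vs 195 ± 53.8). The largest changes were in heat-shock genes, Hspa1b (7.10, 3201 ± 1466 vs 21.5 ± 14.8) and Hspa1a (6.40, 1384 ± 718 vs 15.7 ± 9.51).

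Other genes fell in the wild type islets. The growth factor binding protein Igfbp4 had the lowest log2 fold change of the named genes (-5.12, 9.72 ± 9.47 vs 370 ± 55.1 CPM), followed by Capn3 (-3.61) and Ntn4 (-3.21, 6.62 ± 8.96 vs 72.4 ± 17.3). The cytokine Lta (-2.49, 24.5 ± 21.9 vs 148 ± 36.4, but -1.25 and an adjusted p of 0.150 in cells with a Foxp3 UMI of any T cell cluster), Rcn1 (-2.33), Atp1b1 (-2.29), Treml2 (-2.12) and the survival factor Bcl2 (-2.09, 51.7 ± 34.4 vs 217 ± 60.2) came next. Gpr83 (-1.97, 5 of 6 mice), Kbtbd11 (-1.80), Eno1b (-1.70), Rassf2 (-1.63), the transcription factor Lef1 (-1.43, 93.5 ± 44.6 vs 277 ± 65.8) and the IL-2 receptor chain Il2ra (-1.29, 199 ± 44.8 vs 492.8 ± 39.1) fell too. Foxp3 (-0.39, 460 ± 123 vs 610 ± 94.7, lower in 6 of 6, edgeR adjusted p = 0.0824) was not called. Nrp1 (0.63, 100 ± 54.9 vs 72.8 ± 18.3, higher in 5 of 6, edgeR adjusted p = 0.0824) was not called either. By edgeR 723 of 4322 genes were called (471 higher, 252 lower, 1224 at unadjusted p < 0.05), 484 of them with the same sign in every mouse, against 373 with Treg as cells with a Foxp3 UMI in any T cell cluster. The edgeR adjusted p was 7.38e-16 for Hspa1b, 5.32e-15 for Hspa1a, 9.85e-08 for Il10, 3.54e-09 for Areg, 6.41e-13 for Tigit and 4.62e-12 for Ctla4. It was 1.51e-08 for Ccl5, 5.03e-08 for Ifng, 5.53e-15 for Igfbp4 and 8.94e-08 for Il2ra. Tissue is compared together with its preparation and its mix of clusters, and the largest of 31 other sign assignments of the pairs called 106 genes (real assignment the most of 32).

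**Figure D1:**
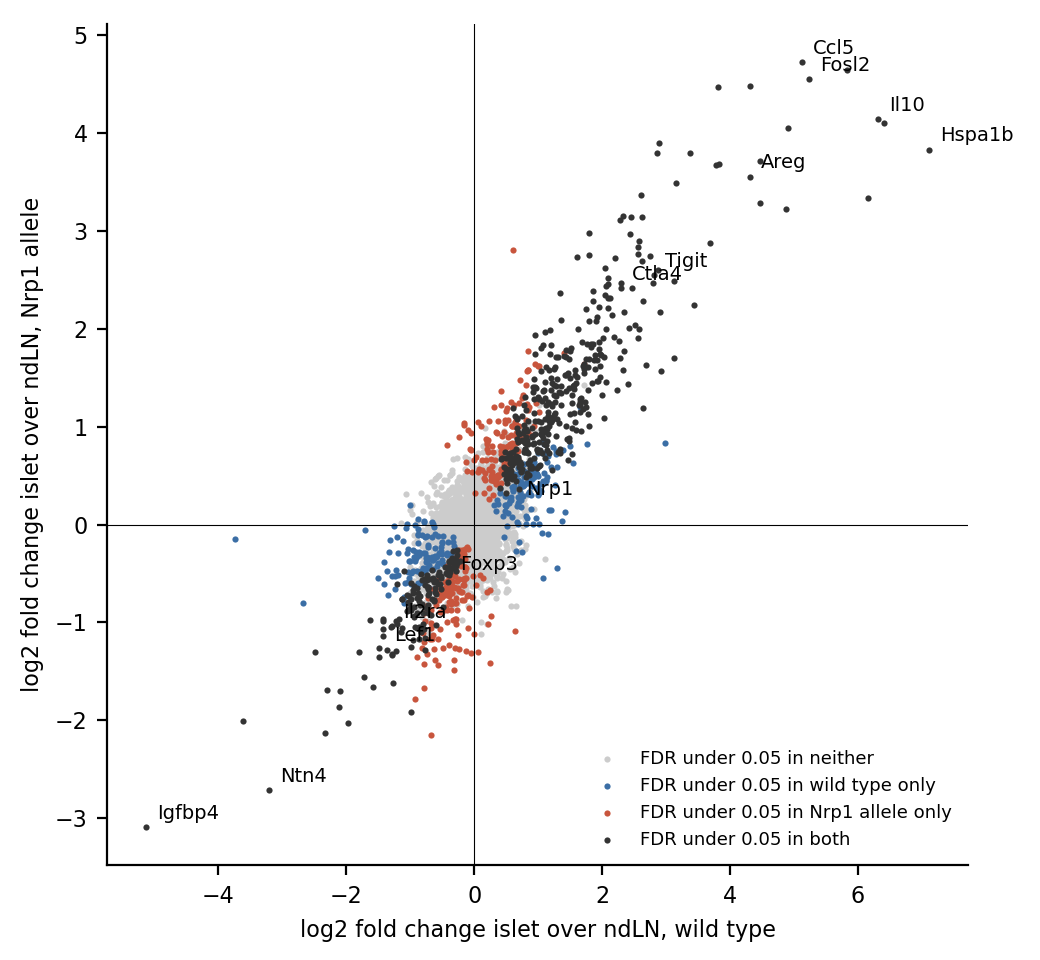
Islet over ndLN log2 fold change (edgeR) of each tested gene in wild type Treg (x axis) and Nrp1 allele Treg (y axis), with points coloured by an adjusted p under 0.05 in both genotypes, wild type only, Nrp1 allele only or neither. Igfbp4 lies at -5.12 and -3.09 and Tigit at 2.81 and 2.55.

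The same question in mice with the Nrp1 allele gave the same program. Il10 rose by a log2 fold change of 4.14 (90.1 ± 56.6 vs 6.08 ± 13.3 CPM, 5 of 6 mice), Areg by 3.55 (196 ± 138 vs 12.4 ± 12.6), Tigit by 2.55 (413 ± 49.4 vs 71.7 ± 29.2), Ctla4 by 2.41 (1433 ± 318 vs 270 ± 33.3) and Lag3 by 3.37 (5 of 6 mice). The smaller Il10 value rests on ndLN mouse 12 (33.2 CPM, others 0 to 3.34), and without mice 1 and 12 the change was 6.38 here. In wild type mice it was 7.58, but only mouse 1 had Il10 in the ndLN (2.63 CPM, others 0). That value is thus against a group at 0, and its size is set by the fit. Ccl5 (4.72, 414 ± 414 vs 16.8 ± 5.58, 5 of 6 mice), Ifng (4.48, 61.8 ± 39.0 vs 2.62 ± 2.12), Cxcr3 (2.42), Cxcr4 (2.87), Cxcl10 (3.71), Bhlhe40 (3.90), Cdkn1a (4.47) and Atf3 (4.65) rose too. The same held for Fosl2 (4.55, 143 ± 68.1 vs 6.21 ± 7.83), Nr4a1 (3.14, 805 ± 178 vs 91.2 ± 40.6) and Tnfaip3 (3.15, 989 ± 235 vs 115 ± 50.6), and for Hspa1a (4.10, 914 ± 541 vs 59.9 ± 58.3) and Hspa1b (3.83, 2074 ± 1092 vs 157 ± 134). Igfbp4 (-3.09, 27.0 ± 28.8 vs 275 ± 67.9), Ntn4 (-2.72), Gpr83 (-2.03), Bcl2 (-1.70), Il2ra (-1.04, 171 ± 73.5 vs 418 ± 79.5) and Lef1 (-0.96) fell. Nrp1 (0.22, 149 ± 48.7 vs 114 ± 26.9, higher in 5 of 6, edgeR adjusted p = 0.562) and Foxp3 (-0.23, 0.322) were not called. By edgeR 776 of 4322 genes were called (492 higher, 284 lower, 1256 at unadjusted p < 0.05), 509 with the same sign in every mouse. The most called by any of 31 other sign assignments was 106. The edgeR adjusted p was 5.07e-10 for Ccl5, 9.74e-08 for Ifng, 3.48e-07 for Il10, 3.19e-07 for Areg, 8.78e-13 for Tigit and 8.85e-13 for Ctla4. It was 4.30e-12 for Hspa1a, 5.31e-12 for Hspa1b, 4.35e-12 for Igfbp4 and 3.11e-06 for Il2ra. The genotypes shared 348 higher genes (53.6 by chance) and 139 lower genes (16.6 by chance), with 0 genes called in opposite directions and a correlation of 0.824 across genes.

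Gene lists put the islet program in groups. In wild type and Nrp1 allele mice in that order, 17 and 18 of 21 Treg effector genes were higher in the islets (20 and 18 adjusted over the list alone, camera adjusted p = 0.000169 and 0.000224 with an estimated correlation). The same held for 8 and 7 of 10 Th1 and interferon gamma genes (8 and 7 adjusted over the list alone, 0.000169 and 0.000224). The NF-kB and TNF family list had 12 and 10 of 14 genes higher and 1 lower in each (12 and 12 higher adjusted over the list alone, 0.00279 and 0.00118). The chemokine receptor and residency list had 9 and 10 of 16 higher and 1 lower in each (9 and 11 higher adjusted over the list alone, 0.00136 and 0.000591). Inhibitory receptors (7 and 6 of 11 higher, 0 and 1 lower, 7 and 8 higher adjusted over the list alone, 0.00279 and 0.00224) and T cell receptor signalling genes (6 and 7 of 15 higher, 2 and 0 lower, the same numbers adjusted over the list alone, 0.0378 and 0.00246) moved the same way. All 11 heat-shock genes (11 adjusted over the list alone in each, 0.000329 and 0.0123) and 12 and 13 of 14 immediate early genes (12 and 13 adjusted over the list alone, 0.00321 and 0.000686) were higher in the islets. Quiescence genes were lower (5 of 16 lower and 1 higher in each, 5 and 6 lower adjusted over the list alone, camera adjusted p = 0.00759 and 0.0160, but 0.254 and 0.244 with an estimated correlation). The Treg core list moved in neither direction, with 3 and 2 of 15 genes higher and 3 and 3 lower (3 and 4 higher, 4 and 3 lower adjusted over the list alone). Its medians of 0.03 and 0.10 were positive while the camera direction was down (adjusted p = 0.745 and 0.830).

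The other lists were not called between the tissues. IL-2 and STAT5 genes split (3 and 4 of 11 higher, 4 and 3 lower, 4 and 4 higher, 5 and 3 lower adjusted over the list alone, camera adjusted p = 0.331 and 0.937). Th17 and Tfh genes (2 and 2 of 3 higher, 1 and 0 lower, the same adjusted over the list alone, 0.309 and 0.105) and type I interferon genes (2 and 0 of 10 higher, 0 and 1 lower, 2 and 0 higher and 1 and 1 lower adjusted over the list alone, 0.348 and 0.560) gave no camera call. Nor did cell cycle genes (1 and 2 of 7 higher, 1 and 1 lower, 1 and 4 higher, 1 and 2 lower adjusted over the list alone, 0.974 and 0.560) or glycolysis genes (1 and 2 of 12 higher, 1 and 0 lower, the same adjusted over the list alone, 0.643 and 0.295). Oxidative phosphorylation genes (1 and 0 of 22 higher, 0 and 1 lower, 1 and 0 higher, 0 and 0 lower adjusted over the list alone, 0.429 and 0.251) and apoptosis genes (2 and 3 of 10 higher, 1 and 2 lower, 2 and 3 higher, 2 and 2 lower adjusted over the list alone, 0.491 and 0.830) were likewise not called. The same held for exocrine genes (0 of 5 called in each, 0 adjusted over the list alone, 0.872 and 0.830). The cell cycle list of wild type mice had a positive median (0.37) and mean while the camera direction was down. Heat-shock UMIs in CPM, a measure of handling as well as of stress, were 16371 ± 4057 (SD, n = 6) in wild type and 13835 ± 3836 (SD, n = 6) in Nrp1 allele islet Treg against 4795 ± 607 and 6472 ± 850 in the ndLN. They were higher in the islets in 6 of 6 mice of each genotype (exact two-sided p = 0.03125, the smallest possible with 6 pairs). Exocrine UMIs in CPM, ambient RNA from the pancreas, were 576 ± 183 and 682 ± 96.3 in islet Treg and 567 ± 125 and 707 ± 115 in ndLN Treg.

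The question in the ndLN was which genes the Nrp1 allele alters in Treg outside the inflamed tissue. Heat-shock genes rose, Hspa1b by a log2 fold change of 2.70 (157 ± 134 (SD, n = 6) vs 21.5 ± 14.8 (SD, n = 6) CPM, edgeR adjusted p = 0.0247) and the Hsp40 chaperone Dnaja1 by 0.73 (541 ± 77.9 vs 323 ± 55.8, 0.0413). The splicing-related gene Rsrp1 rose by 0.86 (366 ± 59.6 vs 197 ± 38.3, 0.000822). The AP-1 gene Junb fell by 0.69 (741 ± 151 vs 1191 ± 180, 0.0148), the phosphatase Dusp1 by 1.01 (198 ± 74.1 vs 387 ± 136, 0.0351) and the cold-inducible gene Cirbp by 0.77 (78.8 ± 13.3 vs 132 ± 30.7, 0.0413). The unannotated gene Gm26740, chosen for naming after values were seen, rose by 0.96 (0.00419). Nrp1 itself was not called (0.66, 114 ± 26.9 vs 72.8 ± 18.3, 194 vs 115 UMIs, 0.304), nor was Foxp3 (0.07, 647 ± 93.2 vs 610 ± 94.7, 0.972). Hsph1 (1.11, 0.0954) and the interferon-induced genes Isg15 (1.39, 0.110) and Rtp4 (1.46, 0.240) were not called. By edgeR 7 of 4322 genes were called (4 higher, 3 lower, 314 at unadjusted p < 0.05), and 99 regroupings of the 12 mice gave at most 2. The count was 3 without cycling cells, 3 without mice 1 and 12 (2 of them shared) and 2 with Treg as cells with a Foxp3 UMI in any T cell cluster. It was 11 with the mean of per-cell CPM, 14 by DESeq2 (5 shared) and 44 with no gene filter beyond 1 UMI. Over 16 alternatives the adjusted p reached 0.154 for Hspa1b and Dnaja1, 0.191 for Junb, 0.327 for Dusp1 and 0.350 for Cirbp, and 0.0264 for Rsrp1.

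Heat-shock genes were the group that moved most with the allele in ndLN Treg (2 of 11 higher, 7 adjusted over the list alone, camera adjusted p = 3.59e-12, and 0.0357 with an estimated correlation). Th1 and interferon gamma genes were higher as a set (0 of 10 called, 0 adjusted over the list alone, 0.00193, and 0.0357 with an estimated correlation, median 0.35). Type I interferon genes were higher (0 of 10 called, 6 adjusted over the list alone, 1.47e-06, but 0.0852 with an estimated correlation). The interferon-response cluster (117 Nrp1 allele and 44 wild type ndLN cells) was in neither class, so its cells are missing from these values. Immediate early genes were lower (2 of 14, 4 adjusted over the list alone, 5.92e-07, but 0.0852 with an estimated correlation), as were T cell receptor signalling genes (0 of 15 called, 2 adjusted over the list alone, 0.00743, but 0.133 with an estimated correlation). Cell cycle genes were lower (0 of 7 called, 0 adjusted over the list alone, 0.0112, but 0.235 with an estimated correlation). Quiescence genes (0 of 16 called, 1 adjusted over the list alone, 0.0466, but 0.470 with an estimated correlation) and exocrine genes (0 of 5 called, 1 adjusted over the list alone, 0.0385, but 0.240 with an estimated correlation) were higher. Neither the Treg core nor the Treg effector list moved (camera adjusted p = 0.902 for each), and the remaining lists gave no call. Heat-shock UMIs in CPM were 6472 ± 850 vs 4795 ± 607 (exact two-sided p = 0.00433), immediate early UMIs 4101 ± 611 vs 5501 ± 777 (exact two-sided p = 0.00866). Exocrine UMIs were 707 ± 115 vs 567 ± 125 (exact two-sided p = 0.0736). The stress genes and the genotype thus move together in these libraries.

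**Figure D2:**
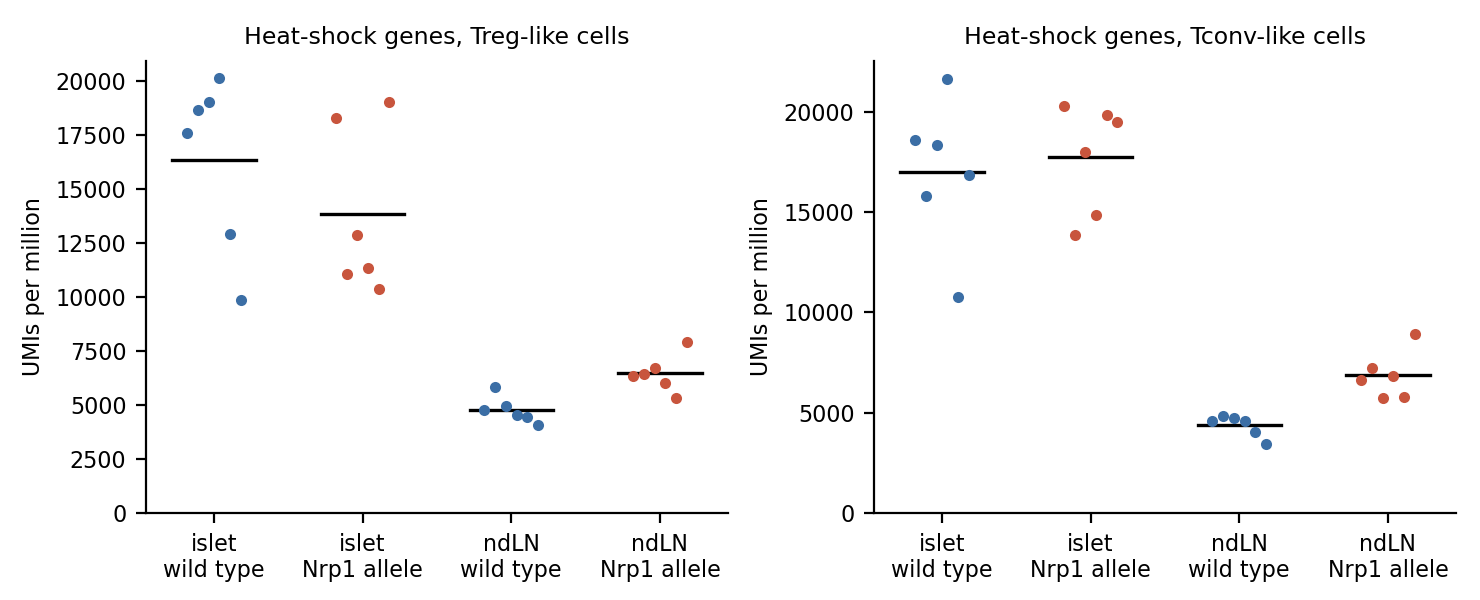
Heat-shock UMIs in CPM (y axis) in Treg-like and Tconv-like cells of each mouse by tissue and genotype (x axis), 1 point per mouse with a line at the mean. In the ndLN the Nrp1 allele groups stood at 6472 ± 850 (Treg) and 6863 ± 1176 (Tconv).

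In the islets the question was whether the Nrp1 allele changes the tissue Treg program. Neither Nrp1 (0.24, 149 ± 48.7 (SD, n = 6) vs 100 ± 54.9 (SD, n = 6) CPM, 120 vs 78 UMIs, edgeR adjusted p = 0.999) nor Foxp3 (0.23, 557 ± 153 vs 460 ± 123, 0.987) was called. No gene was called by edgeR (0 of 4322, 234 at unadjusted p < 0.05) or by DESeq2 (0, 173 at unadjusted p < 0.05), but 13 were with no gene filter beyond 1 UMI and 1 without mice 1 and 12. The heat-shock list was lower by camera (0 of 11 called, 0 adjusted over the list alone, median -0.28, adjusted p = 0.00709, but 0.847 with an estimated correlation), and quiescence gave 0.0885. The other lists gave no call with adjusted p of 0.302 or more. The libraries are small, 5 Treg in mouse 11 and 8 in mouse 6. In simulated data 63% of 2-fold and 92% of 4-fold changes were recovered in islet Treg against 83% and 97% in ndLN Treg. The simulation used a single mean profile and a spread estimated over the Treg of both tissues. Recovery in the islets is overstated if the spread is larger there. A regrouping of the 12 mice called as many as 27 genes.

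The difference of the differences asked whether the Nrp1 allele acts differently on islet and ndLN Treg. Hspa1b had a smaller islet against ndLN change with the allele (-3.28, edgeR adjusted p = 0.0128) and Junb a larger one (0.97, 0.0144). The T cell receptor segment Trbv13-3, chosen for naming after values were seen, also differed (3.59, 0.0128, but 2.49, 0.804 in cells with a Foxp3 UMI of any T cell cluster), while Nrp1 did not (-0.42, 1.00). By edgeR 3 of 4322 genes were called (2 higher, 1 lower, 204 at unadjusted p < 0.05), against 8 including the same 3 with the mouse as a block, and no regrouping of 99 called more than 1. The count was 1 without cycling cells, without mice 1 and 12, and with Treg as cells with a Foxp3 UMI in any T cell cluster, but 7 with the mean of per-cell CPM and 13 with no gene filter beyond 1 UMI. Heat-shock genes differed as a list (1 of 11 lower, 6 adjusted over the list alone, camera adjusted p = 6.32e-17, and 0.0167 with an estimated correlation). Interferon genes (0 of 10 called, 0 adjusted over the list alone, 0.00729, but 0.438 with an estimated correlation) were called by camera at the preset correlation only. So were immediate early genes (1 of 14 called, 3 adjusted over the list alone, 9.67e-05, but 0.269 with an estimated correlation) and T cell receptor signalling genes (0 of 15 called, 2 adjusted over the list alone, 0.0166, but 0.269 with an estimated correlation).

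Nrp1 was then followed cell by cell as RNA. Among ndLN Treg, 26.04% (95% interval 22.2 to 30.2) of Nrp1 allele cells and 17.3% (13.8 to 21.2) of wild type cells carried an Nrp1 UMI. Among islet Treg it was 29.0% (23.5 to 35.0) and 27.7% (21.2 to 34.9). Median depths were 3131.5, 3317, 2947 and 3052 UMIs. Tconv-like cells carried Nrp1 UMIs in 4.07% and 1.21% of ndLN cells and 14.3% and 21.8% of islet cells of Nrp1 allele and wild type mice. This class is not free of Foxp3. A Foxp3 UMI was in 14.1% of the Ccl5 and Cxcr6 cluster and 11.3% of the Xcl1 and Il21 cluster. In the Dapl1 clusters it was in 1.96% and 3.03%. With Tconv limited to cells without a Foxp3 UMI, wild type islet Treg with one did not differ from them in Nrp1 (-0.0733, edgeR adjusted p = 0.962). Treg without a Foxp3 UMI could still be among them. Thinning to 2000 UMIs left out shallower cells, 78 Nrp1 allele and 66 wild type ndLN Treg and 54 and 37 islet Treg. After thinning, the per-mouse ndLN Treg share was 20.5 ± 4.18% (SD, n = 6) against 11.3 ± 2.85% (SD, n = 6) (exact two-sided p = 0.00216, the smallest possible with 6 against 6, BH 0.0563 over 26 tests in both classes). Without thinning it was 26.01 ± 6.45% against 16.8 ± 3.85% (exact p = 0.0130, BH 0.197). In the islets the thinned shares were 31.9 ± 21.8% against 13.4 ± 7.11% (exact p = 0.0108, BH 0.281) and the unthinned shares 37.4 ± 21.7% against 24.1 ± 12.5% (exact p = 0.277). In wild type Tconv the Nrp1 share was 21.3 ± 14.3% in the islets and 1.28 ± 1.01% in the ndLN (exact p = 0.03125, BH 0.0542). Ctla4 was seen in 79.3 ± 7.03% of islet and 47.8 ± 7.54% of ndLN wild type Treg, Tigit in 50.6 ± 15.1% and 9.84 ± 4.56%, and Icos in 59.5 ± 12.1% and 25.6 ± 11.4% (each exact p = 0.03125, BH 0.0542). Nrp1 allele Treg gave 79.4 ± 10.9% and 42.6 ± 6.57% for Ctla4, 43.8 ± 8.07% and 9.07 ± 3.09% for Tigit, and 64.9 ± 18.3% and 22.5 ± 4.38% for Icos (each exact p = 0.03125, BH 0.0677).

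Surface Nrp1, read as antibody tag counts per cell, asked whether the protein follows the allele and the tissue. This measure was examined after the RNA values were seen. The median count in ndLN Treg was 37.6 ± 2.63 (SD, n = 6) with the Nrp1 allele and 21.8 ± 4.19 (SD, n = 6) in wild type, a ratio of 1.73 with no overlap between mice (exact two-sided p = 0.00216). Wild type islet Treg stood at 10.8 ± 1.17, lower than ndLN Treg in 6 of 6 mice (ratio 0.498, exact p = 0.03125) and near the Tconv values of 9.58 ± 1.02 in the islets and 9.67 ± 1.03 in the ndLN. The second hashtag fell too on wild type islet Treg (210 ± 73.3 against 717 ± 179 counts, ratio 0.293, 6 of 6 mice). As excess over Tconv per 100 hashtag counts the tissues were not called apart (0.820 ± 1.21 against 1.71 ± 0.357, lower in 5 of 6, exact p = 0.125). Nrp1 allele islet Treg stood at 26.3 ± 24.7 (ratio 2.43 to wild type, exact p = 0.0108, ratio 0.701 to ndLN, exact p = 0.344), but mouse 11 gave 76 from 5 cells. Without libraries of fewer than 10 cells the values were 16.4 ± 5.04 (SD, n = 5) against 10.8 ± 1.30 (SD, n = 5) (ratio 1.52, exact p = 0.0317). The second hashtag on islet Treg was itself 2.32 times as high with the allele (487 ± 163 (SD, n = 6) against 210 ± 73.3 (SD, n = 6) counts, exact p = 0.00433). The islet genotype difference of the tag was not called as a ratio to isotype (2.81 ± 0.868 against 2.15 ± 0.496, exact p = 0.130) or as excess over Tconv per 100 hashtag counts (2.93 ± 3.45 against 0.820 ± 1.21, exact p = 0.156). Nor was it in the S100a4, Itgae and Ccr6 cluster (10.4 ± 0.548 (SD, n = 5) against 10.0 ± 1.30 (SD, n = 6) tag counts, exact p = 0.589). In libraries of at least 10 cells the Nrp1 allele islets compare as 16.4 against 38.2 ± 2.41 in the ndLN (ratio 0.429, lower in 5 of 5, exact p = 0.0625, the smallest possible with 5 pairs). The share of Treg above the 95th percentile of Tconv was 5.49 ± 3.27% and 25.6 ± 20.5% in wild type and Nrp1 allele islets (exact p = 0.0173) and 42.3 ± 4.92% and 67.6 ± 3.09% in the ndLN (exact p = 0.00216). The islet shares were not repeated without mouse 11 and its 5 cells, nor scaled to the hashtag. Their genotype difference therefore cannot be told apart from that mouse or from stronger labelling. The cut differed between the tissues, so islet and ndLN shares are not compared. Isotype counts in Treg were 4.75 ± 0.418, 5.75 ± 1.08, 5.75 ± 0.612 and 5.50 ± 0.548, and Tconv of the Nrp1 allele stood at 10.5 ± 1.05 and 10.0 ± 0.632.

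**Figure D3:**
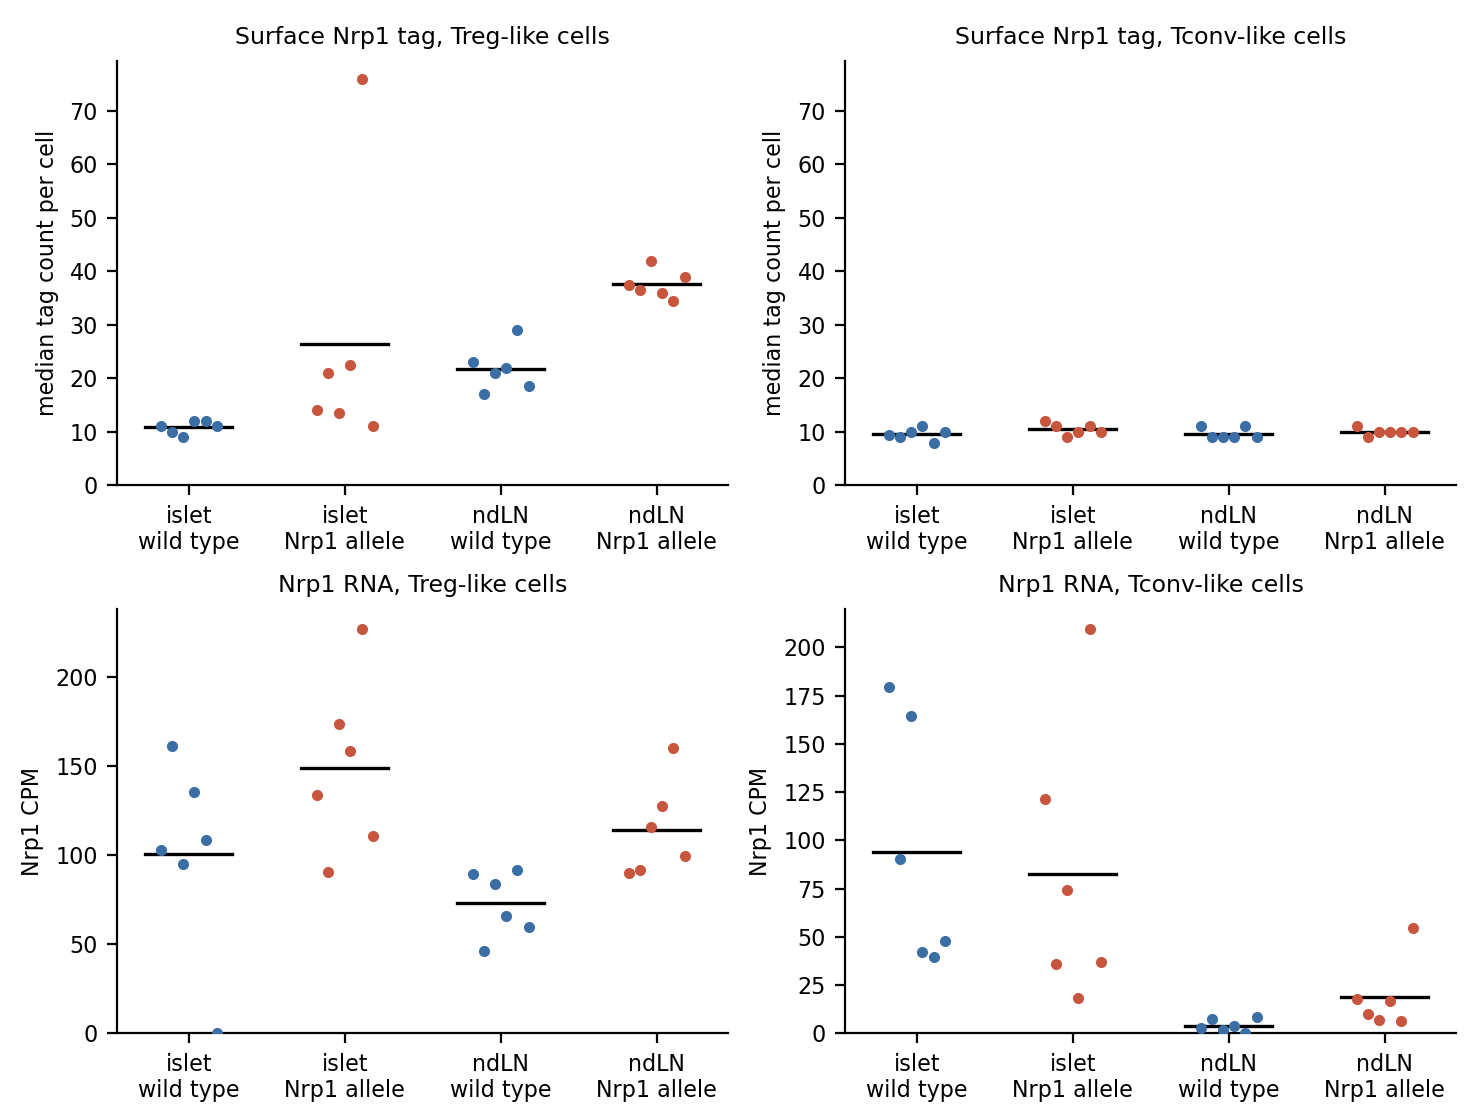
Nrp1 in Treg-like and Tconv-like cells of each mouse by tissue and genotype (x axis), as median surface tag counts per cell (y axis, upper row) and as RNA in CPM (y axis, lower row), 1 point per mouse with a line at the mean. Treg tag values in the ndLN were 37.6 ± 2.63 and 21.8 ± 4.19 with and without the Nrp1 allele.

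Tconv of the ndLN, which should not express the transgene, answered whether genotype differences are limited to Treg. Heat-shock genes rose here as in Treg, Hspa1b by a log2 fold change of 2.66 (308 ± 120 (SD, n = 6) vs 48.0 ± 15.8 (SD, n = 6) CPM, edgeR adjusted p = 2.05e-06) and Hspa1a by 2.32 (133 ± 40.3 vs 26.6 ± 14.3, 7.96e-05). Hsph1 rose by 1.29 (167 ± 39.2 vs 68.7 ± 15.3, 0.00681), Dnaja1 by 0.98 (558 ± 81.7 vs 277 ± 73.8, 3.80e-05), Hspa8 by 0.74 (0.000288) and Hsp90ab1 by 0.53 (0.0334). The phosphatases Dusp1 (-0.77, 189 ± 60.0 vs 322 ± 48.8, 0.0392) and Dusp2 (-0.79, 216 ± 70.7 vs 372 ± 39.2, 0.0269) and the histone gene H3f3b (-0.48, 1149 ± 74.5 vs 1601 ± 99.05, 0.00681) fell. Nrp1 (2.21, 18.7 ± 18.2 vs 3.97 ± 3.19, 32 vs 7 UMIs, 0.639) and the Nrp1 ligand Sema4a (0.33, 0.981) were not called. By edgeR 9 of 4647 genes were called (6 higher, 3 lower, 275 at unadjusted p < 0.05), and no other grouping of 99 called more than 1. The count was 5 without mice 1 and 12, and 14 to 45 at a hashtag ratio of 10, by DESeq2, in the Foxp3 UMI classes of any T cell cluster, with the interferon cluster as Tconv and with no gene filter. As lists, heat-shock genes were higher (6 of 11, 9 adjusted over the list alone, camera adjusted p = 3.72e-37, and 0.000199 with an estimated correlation). Interferon genes (0 of 8 called, 0 adjusted over the list alone, 0.000638, but 0.113 with an estimated correlation) and Th1 genes (0 of 11 called, 0 adjusted over the list alone, 0.0246, but 0.261 with an estimated correlation) were higher. Cells of the interferon-response cluster (117 Nrp1 allele and 44 wild type ndLN cells) are missing from these values. Immediate early genes (1 of 14 lower, 6 adjusted over the list alone, 1.98e-06, but 0.113 with an estimated correlation) and T cell receptor signalling genes (1 of 15 lower, 3 adjusted over the list alone, 0.0232, but 0.225 with an estimated correlation) were lower. Semaphorin and plexin genes gave no call (0 of 3 called, 1 adjusted over the list alone, 0.151). Heat-shock UMIs in CPM were 6863 ± 1176 vs 4381 ± 535 (exact two-sided p = 0.00216) and immediate early UMIs 3884 ± 757 vs 5325 ± 785 (exact p = 0.0152).

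Tconv of the islets answered the same question in the inflamed tissue. Ccl4, a chemokine of activated T cells, was chosen for naming after values were seen. It fell by 3.82 (edgeR adjusted p = 3.64e-07) and was the only gene called (0 higher, 1 lower, 372 of 4647 at unadjusted p < 0.05). At a hashtag ratio of 10, without mice 1 and 12 and with the Foxp3 UMI classes of any T cell cluster Ccl4 was under the gene filter and 0 genes were called, while 40 were with no gene filter beyond 1 UMI. Nrp1 (-0.50, 82.7 ± 72.3 (SD, n = 6) vs 94.0 ± 63.4 (SD, n = 6) CPM, 0.801) and Sema4a (0.16, 32.9 ± 14.0 vs 26.7 ± 14.3, 0.969) were not called. The shares of cells with a Ccl4 UMI were 2.67 ± 2.12% vs 7.19 ± 3.91% (exact two-sided p = 0.0303, BH 0.394 over 26 tests in both classes) and with a Tigit UMI 16.4 ± 5.97% vs 29.0 ± 8.56% (exact p = 0.0152, BH 0.394). Lists called by camera at the preset correlation were Treg effector genes, lower (0 of 14 called, 2 adjusted over the list alone, 0.00207, but 0.414 with an estimated correlation), and inhibitory receptors, lower (0 of 11 called, 3 adjusted over the list alone, 0.0132, but 0.479 with an estimated correlation). Quiescence genes were called as higher (0 of 16 called, 1 adjusted over the list alone, 0.000126, but 0.479 with an estimated correlation). Semaphorin and plexin genes gave no call (0 of 3 called, 0 adjusted over the list alone, 0.484). Heat-shock UMIs in CPM were 17725 ± 2727 vs 16986 ± 3639. Regroupings of the mice called as many as 105 genes, with 28 of 100 groupings calling at least 1.

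Treg and Tconv of the same tissue and genotype were compared to place the classes, which were set by Foxp3 in the clusters. The clusters were made from the same expression values with the Treg and Tconv markers added. The values of such markers and lists therefore describe the classes and are not independent support for them. In islet wild type, islet Nrp1 allele, ndLN wild type and ndLN Nrp1 allele in that order, Foxp3 rose by 3.79, 4.19, 4.75 and 4.90 (edgeR adjusted p = 2.97e-15, 2.11e-19, 4.66e-24 and 2.52e-24). Its values were 436 ± 118 (SD, n = 6) vs 29.6 ± 27.2 (SD, n = 6), 527 ± 150 vs 41.6 ± 33.8, 590 ± 92.6 vs 21.8 ± 13.1 and 625.2 ± 86.4 vs 20.3 ± 10.4 CPM. Il2ra rose by 2.28, 2.67, 5.05 and 5.27 and Ctla4 by 2.17, 2.61, 3.31 and 3.38. The naive gene Igfbp4 was lower (-5.24, -4.45, -2.08 and -2.51). Nrp1 was higher in ndLN Treg than in ndLN Tconv (4.002, adjusted p = 8.07e-08, 70.5 ± 17.5 vs 4.20 ± 3.37 CPM in wild type, and 2.46, 9.03e-07, 110 ± 26.5 vs 19.7 ± 19.2 with the allele). It was not called in the islets (0.05, 0.980; 0.80, 0.137). Sema4a was lower in Treg (-2.07, adjusted p = 0.0530, not called, then -1.72, 0.0195, -2.15, 6.94e-05 and -2.36, 4.52e-06). By edgeR 248, 498, 753 and 737 of 5548 genes were called (147, 264, 415 and 400 higher; 145 in islet wild type with the Foxp3 UMI classes of any T cell cluster), against at most 14, 127, 45 and 2 in 31 other sign assignments. Treg core genes were higher in 13, 13, 15 and 15 of 15 (13, 14, 15 and 15 adjusted over the list alone, camera adjusted p = 2.99e-11, 2.51e-09, 2.41e-14 and 4.00e-16 with an estimated correlation). Treg effector genes were higher in 11, 14, 14 and 14 of 21 (14, 16, 18 and 19 adjusted over the list alone, 0.000399, 5.42e-05, 4.90e-05 and 8.33e-05) and IL-2 and STAT5 genes in 4, 4, 7 and 8 of 11 (4, 6, 7 and 8 adjusted over the list alone, 0.0364, 0.0134, 1.33e-08 and 9.11e-09). Quiescence genes were lower in 3, 8, 8 and 6 of 16 (6, 11, 10 and 7 adjusted over the list alone, camera adjusted p = 0.00199, 2.38e-05, 2.49e-07 and 0.000426, but 0.287, 0.131, 0.0622 and 0.192 with an estimated correlation). Heat-shock genes were lower in Nrp1 allele islet Treg than Tconv (3 of 11, 3 adjusted over the list alone, 0.000242, but 0.166 with an estimated correlation). Semaphorin and plexin genes gave no call in any group (adjusted p = 0.786, 0.208, 0.369 and 0.334).

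The make-up of the samples was compared to ask whether the allele alters the T cell classes. Treg-like cells were 29.5 ± 4.98% (SD, n = 6) of Nrp1 allele and 35.5 ± 8.52% (SD, n = 6) of wild type islet cells (exact two-sided p = 0.171), and 35.6 ± 3.46% and 35.0 ± 11.9% of ndLN cells (exact p = 0.963). In Nrp1 allele mice they were lower in the islets than in the ndLN by 6.18 points in 6 of 6 mice (exact p = 0.03125), a call lost at Leiden resolution 0.6 (-5.59, exact p = 0.0625). In wild type mice the difference was 0.495 points (exact p = 0.906), and -4.45 at resolution 1.5 (exact p = 0.344). Between genotypes in the ndLN it was -1.71 points at that resolution. Tconv-like cells were 54.9 ± 7.32% and 51.5 ± 8.72% of islet cells and 38.6 ± 3.90% and 45.9 ± 8.58% of ndLN cells (exact p = 0.0519 in the ndLN). The interferon-response cluster was larger in Nrp1 allele ndLN (8.75 ± 3.70% against 3.58 ± 0.942%, exact p = 0.00216, BH 0.0346 over 16 clusters). In the islets it was not called (2.21% against 0.929%, exact p = 0.346). Cells with an Mki67 or Top2a UMI were 10.98 ± 9.94% of Nrp1 allele and 19.2 ± 9.77% of wild type islet Treg (exact p = 0.186) and 6.78% and 8.62% of ndLN Treg. These shares leave out the cycling cluster (38 Nrp1 allele and 21 wild type islet cells), which was in neither class. Of all its cells 38.75% had a Foxp3 UMI, so the shares do not measure cycling among all Treg. Since Treg and Tconv were mixed at loading, these shares describe the loaded cells.

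The T cell receptors were read to ask whether clones expand in the islets and are shared. Of 3292 called cells with a contig, 2631 had a single beta chain and at least 1 alpha chain, and 2327 of these, in 2244 clonotypes, fell in the classes. Islet Treg were in expanded clones in 6 of 118 wild type cells (5.08%, 95% interval 1.89 to 10.7) and 18 of 181 Nrp1 allele cells (9.94%, 6.00 to 15.3, 7.23% when drawn to 118 cells). Per mouse the values were 5.49 ± 6.54% (SD, n = 6) and 8.19 ± 9.31% (SD, n = 6) (exact two-sided p = 0.610). At a hashtag ratio of 10 wild type islet Treg were expanded in 2 of 85 cells (2.35%, per mouse 2.38 ± 5.83%) and Nrp1 allele islet Treg in 16 of 169 (9.47%, 7.49 ± 7.37%, exact p = 0.197). Islet Tconv were expanded in 31 of 175 wild type cells (17.7%, drawn 14.1%, largest clone 6 cells) and 29 of 336 Nrp1 allele cells (8.63%, drawn 5.62%, largest 7). Of those 29 cells 25 came from mouse 7 (25 of its 116 cells), while mouse 8 had 0 of 105. The pooled and drawn values with the allele thus rest mostly on 1 mouse. Per mouse the values were 16.1 ± 11.7% and 5.71 ± 8.49% (exact p = 0.123). In the ndLN, Treg were expanded in 6 of 330 (1.82%) and 2 of 334 cells (0.599%, but 6 cells by the beta chain alone and 4 by the deposited clonotype number, exact p = 0.545). Tconv were expanded in 14 of 456 (3.07%, but 8 of 424, 1.89%, at a hashtag ratio of 10) and 15 of 397 (3.78%, exact p = 0.535). Between tissues the per-mouse values gave exact p = 0.313 and 0.125 for wild type and Nrp1 allele Treg, and 0.0625 and 0.813 for Tconv. Islet and ndLN Treg shared 0 of 442 wild type and 0 of 504 Nrp1 allele clonotypes (2.30 and 4.58 with shuffled tissue), and Tconv 1 of 604 and 0 of 705. Treg and Tconv shared 3 of 268 and 4 of 483 islet clonotypes, all within a mouse (9.58 and 10.96 with shuffled class), and 2 of 774 and 0 of 722 in the ndLN. The genotypes shared 1 of 471 islet Tconv clonotypes and 0 of the other classes, which is the background for chance or doublets. Shuffled values describe random mixing of clones over both groups and are not that background.

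**Figure D4:**
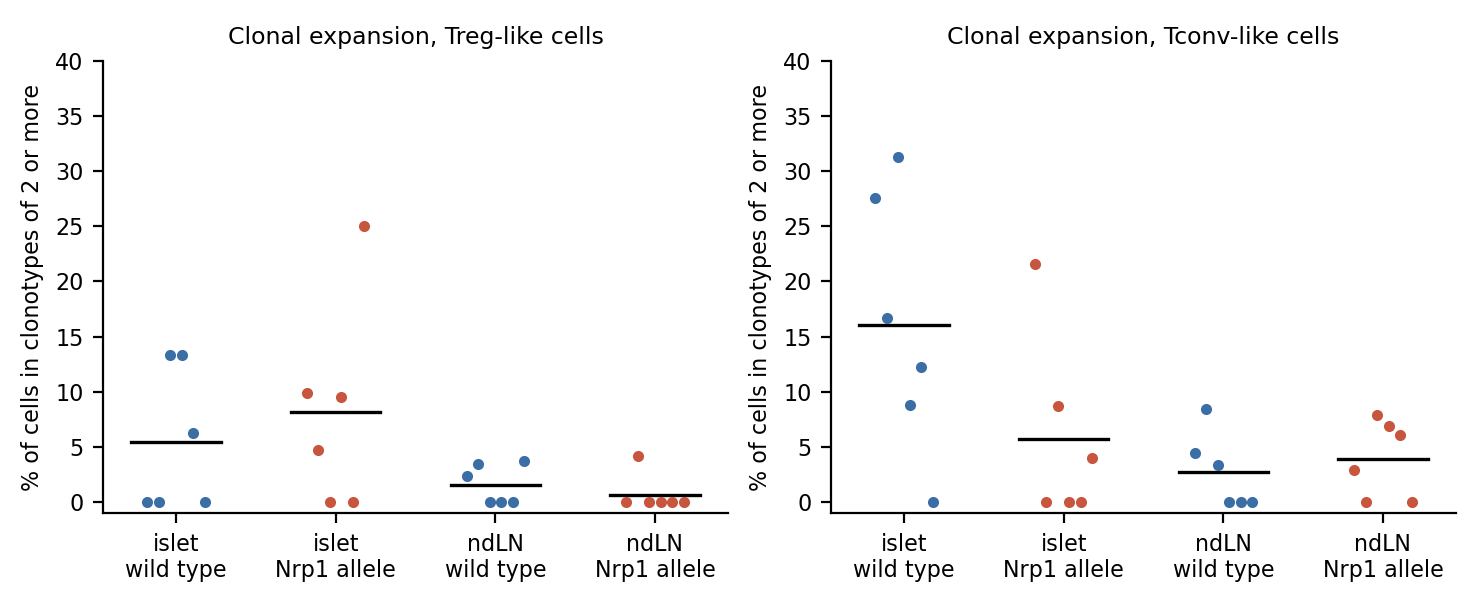
Percent of Treg-like and Tconv-like cells in expanded clonotypes (y axis) of each mouse by tissue and genotype (x axis), 1 point per mouse with a line at the mean. Wild type islet Tconv stood at 16.1 ± 11.7% and Nrp1 allele islet Tconv at 5.71 ± 8.49%.

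The receptor contigs were also used to place the Trbv13-3 difference, after the RNA value was seen. They come from the same cells, so the islet Treg test restates the RNA difference and is not independent support. The segment was used by 16 of 181 Nrp1 allele islet Treg in 15 clonotypes and by 1 of 118 wild type islet Treg, per mouse 7.77 ± 6.40% (SD, n = 6) and 0.575 ± 1.41% (SD, n = 6) (exact two-sided p = 0.0152). In ndLN Treg it was 6.31 ± 5.04% and 10.1 ± 2.69% (exact p = 0.128) and in islet Tconv 4.14% and 3.61% (exact p = 0.807).

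The genes that carry the results sit at these mm10 positions. Nrp1 is ENSMUSG00000025810 (8:128358591-128505476), Foxp3 ENSMUSG00000039521 (X:7579676-7595243), Sema4a ENSMUSG00000028064 (3:88435959-88461182) and Ccl4 ENSMUSG00000018930 (11:83648624-83664683). Rsrp1 is ENSMUSG00000037266 (4:134923625-134927370), Dnaja1 ENSMUSG00000028410 (4:40722468-40734965), Hspa1b ENSMUSG00000090877 (17:34956429-34959238), Hspa1a ENSMUSG00000091971 (17:34969359-34972156), Hsph1 ENSMUSG00000029657 (5:149616843-149636498), Cirbp ENSMUSG00000045193 (10:80165990-80172786), Junb ENSMUSG00000052837 (8:84976909-84978748) and Dusp1 ENSMUSG00000024190 (17:26505591-26508472). Il10 is ENSMUSG00000016529 (1:131019845-131024970), Areg ENSMUSG00000029378 (5:91139599-91148432), Ctla4 ENSMUSG00000026011 (1:60909025-60915832), Tigit ENSMUSG00000071552 (16:43626137-43665125), Ccl5 ENSMUSG00000035042 (11:83525778-83530518), Ifng ENSMUSG00000055170 (10:118441046-118445894), Igfbp4 ENSMUSG00000017493 (11:99040005-99052655) and Il2ra ENSMUSG00000026770 (2:11642792-11693194).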

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

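The tests of handling and of an effect inside Treg for the heat-shock genes, of staining as the whole of the surface tag difference (over all Treg and within a cluster), and of a sequence variant at Ccl4 were chosen only after the results were seen, while the predictions of the other tests were written before those tests were run. A mouse far from the other mice of its group by Dixon's ratio was looked for in 64 groups of per-mouse values and 239 groups of gene values, and chance alone flags about 1 in 20 groups, against 11 and 20 found.

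The antibody tag against Nrp1 had 1 such mouse, mouse 11 of the Nrp1 allele islets at 76 counts (others 11 to 22.5). Pancreatic RNA in called cells stood out in several samples. Exocrine UMIs in CPM were 24067 in wild type islets of mouse 1 (others 560 to 1403), 3827 in Nrp1 allele islets of mouse 12 (590 to 1249), 1310 in wild type ndLN of mouse 5 (590 to 834) and 5713 in Nrp1 allele ndLN of mouse 12 (694 to 1066). Beta cell UMIs in CPM were 272 in wild type islets of mouse 1 (0 to 7.23), 26.1 in Nrp1 allele islets of mouse 12 (0 to 6.08), 28.3 in wild type ndLN of mouse 1 (0 to 4.98) and 39.5 in Nrp1 allele ndLN of mouse 7 (0 to 7.25). Mouse 10 gave 75 Tconv-like cells in the Nrp1 allele ndLN (others 86 to 90), and mouse 8 was the only mouse of that group with expanded Treg (4.17%, others 0).

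In islet Treg single genes stood apart in 1 mouse of a group. Wild type mouse 5 had Bhlhe40 at 923 CPM (others 242 to 479) and Cxcl10 at 429 (36.7 to 135), mouse 2 had Capn3 at 14.7 (0 to 5.43), and mouse 1 had Trbv13-3 at 66.5 (0 to 12.3). Nrp1 allele mouse 12 had Foxp3 at 859 (448 to 544) and mouse 10 had Rtp4 at 88.0 (21.3 to 46.2). In wild type ndLN Treg, mouse 3 had Bcl2 at 99.3 (220 to 265), Cxcr3 at 107 (7.99 to 39.8) and Tigit at 115 (39.8 to 66.0), mouse 1 had Il10 at 2.63 (0), mouse 2 had Nr4a2 at 23.2 (7.33 to 13.1) and mouse 6 had Treml2 at 43.9 (84.3 to 103). In Nrp1 allele ndLN Treg, mouse 12 had Bhlhe40 at 87.0 (11.6 to 38.6), Gem at 53.9 (11.96 to 19.3) and Il10 at 33.2 (0 to 3.34), mouse 8 had Cxcr3 at 67.6 (8.97 to 30.9), and mouse 11 had Kbtbd11 at 194 (135 to 155) and Tigit at 16.7 (72.4 to 104). In Nrp1 allele ndLN Tconv, mouse 9 had Ccl4 at 3.47 (0) and mouse 12 had Nrp1 at 54.7 (6.47 to 17.7).

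The islet against ndLN difference itself differed between the genotypes for the genes Trbv13-3 (3.59, edgeR adjusted p = 0.0128), Junb (0.97, 0.0144) and Hspa1b (-3.28, 0.0128). On the log2 scale it differed for the second hashtag of Treg (1.28, exact p = 0.00216), for heat-shock UMIs of called cells (-0.367, exact p = 0.0238), Treg (-0.675, exact p = 0.00433) and Tconv (-0.563, exact p = 0.0238), and for immediate early UMIs of called cells (0.572, exact p = 0.0173), Treg (0.460, exact p = 0.0152) and Tconv (0.439, exact p = 0.0455). In percent points it differed for the interferon-response cluster (-3.88, exact p = 0.00433, BH 0.0693), the share of Tconv-like cells (10.7, exact p = 0.0346), and Tconv with a Tigit UMI (-14.1, exact p = 0.0130, BH 0.281) or a Ccl4 UMI (-4.71, exact p = 0.0216, BH 0.281).

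Surface Nrp1 was lower on islet than on ndLN Treg of wild type mice (ratio 0.498). A different mix of the Treg clusters fell short as the whole of the difference. Within the S100a4, Itgae and Ccr6 cluster the ratio was 0.343 (10.0 ± 1.30 against 29.2 ± 6.74 counts, exact p = 0.03125). Treg states that differ between the tissues inside that cluster were not tested apart. That cluster held 39 wild type islet cells. The Il10 and Ctla4 cluster held 107, but only 4 wild type ndLN cells, and was not compared. A part played by the mix of states stays open. Weaker staining of islet cells in general could not be excluded, because the second hashtag on islet Treg was also lower. Its median ratio was 0.297 in wild type mice, further down than the Nrp1 tag (0.512), and 0.499 over all 12 mice, while the isotype control fell less (0.826 in wild type). As the whole of the difference over all Treg it stayed open too. The islet to ndLN ratio of the Nrp1 excess over Tconv was below that of the hashtag in 5 of 6 wild type mice (0.115 against 0.297, exact p = 0.0625). It was below in 10 of all 12 mice (0.125 against 0.499), but with mouse 11 and its 76 counts from 5 cells the exact p was 0.536. Within the S100a4, Itgae and Ccr6 cluster, which has no islet cell of mouse 11, weaker labelling fell short of the whole difference if Tconv counts are background in both tissues. Whether they are was not tested, so it is not excluded. Wild type Tconv carried Nrp1 RNA at 39.3 to 180 CPM in the islets and 0 to 8.28 in the ndLN. Their tag counts were 9.58 ± 1.02 and 9.67 ± 1.03. There the excess fell further than the hashtag on the same cells in 11 of 11 mice (median ratio 0 against 0.382, exact p = 0.00098), and in 6 of 6 wild type mice (0.0442 against 0.314, exact p = 0.03125), with 1 to 27 islet cells per mouse. Weaker labelling as part of the difference stays open, because the hashtag falls too. Loss of the protein in the islets and its loss during islet preparation would give the same values, and neither was tested.

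Heat-shock genes rose in ndLN cells of the Nrp1 allele. An effect of Nrp1 confined to Treg was excluded, since the log2 rise in Treg exceeded that in Tconv by -0.196 (0.719 against 0.915; exact p = 0.186). A difference in handling of the nodes of the 2 genotypes, which should reach all cells, was consistent with the Tconv rise of 0.915. An indirect effect of the allele on all T cells of the node would give the same values and was not tested.

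Ccl4 was lower in islet Tconv of the Nrp1 allele. Fewer cells of the Xcl1 and Il21 cluster as the whole cause would leave Ccl4 alike within it. There Ccl4 still differed by -4.24 on the log2 scale (68.6 ± 132 against 1294 ± 1424 CPM, 74 and 69 cells, exact p = 0.00433). That test reuses the UMIs for which Ccl4 was chosen, and Ccl4 was among the top genes of the cluster. It therefore cannot exclude this cause. The cluster was smaller with the allele (8.87% against 14.2% of islet cells), so the cause stays open as a whole or a part. Few cells carried it, 16 of 175 wild type islet Tconv with a called receptor. Expanded wild type clones held 30.6% of the Ccl4 UMIs with a called receptor (121 of 396), and the largest clonotype alone held 28.5%, so clones could account for part of it and the test stays open. A sequence variant that lowers Ccl4 in every cell stays open as well, with islet Treg at a log2 ratio of 2.56 in the opposite direction (86.0 ± 123 against 14.6 ± 14.9 CPM; exact p = 0.236).

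Regrouping the same mice showed how often other groupings called as many genes in the main setting. Regroupings were not run in the other settings. In those the real count fell as low as 2 in ndLN Treg and 1 for the difference of the differences, so chance is not excluded there. For the genes called in ndLN Treg (7) and ndLN Tconv (9) and the difference of the differences (3), 1 of 100 groupings, the real one, gave as many, and the most in any other was 2, 1 and 1. The islet against ndLN comparisons (723 and 776) and Treg against Tconv (248, 498, 753 and 737) were reached in 1 of 32 sign assignments, the real one, with at most 106 and 106, and 14, 127, 45 and 2, in another. For Treg against Tconv these counts say nothing of chance. Those classes were cut from clusters of the same expression values, which favors the real assignment in advance. The 1 gene of islet Tconv was reached in 28 of 100. For islet Treg nothing could be tested, since a count of 0 is reached in 100 of 100 groupings by definition. Other groupings called up to 27 genes in islet Treg and 105 in islet Tconv, many more than the genotype. That points to a structure of the samples or to the noise of small libraries, which were not tested apart.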

How the results depend on the processing

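Alternatives chosen after the data were examined were a Foxp3 UMI in any T cell cluster, the classes at other resolutions, the interferon cluster as Tconv, library size, mice 1 and 12, and all those for the difference of the differences, Treg against Tconv, the surface tag and the stress UMIs. The others were chosen before. Over 205 reported results and 2599 alternatives, 2430 were unchanged, 113 became weaker, 16 stronger, 12 reversed and 28 moved. Genes left out of the report are not counted. Unchanged means the same direction and side of the threshold, except for counts, which have neither. Counts of called genes were unchanged within a factor of 1.5 (154 of 181 alternatives). For shared clonotypes 35 of 36 alternatives were entered as unchanged, although some counts differed. Wild type islet Treg and Tconv shared 3 clonotypes in the main setting and 1 at a hashtag ratio of 10. Immediate early UMIs were unchanged in all of their alternatives (16), gene lists in 589 of 654 and single genes in 1472 of 1533. Clonal expansion had no call in any of 24 alternatives, as in the main setting, which says nothing of its stability. The counts of called genes ran from 0 to 13 in islet Treg, 2 to 44 in ndLN Treg, 373 to 882 and 533 to 916 between tissues, 1 to 13 for the difference of the differences, 0 to 40 in islet Tconv, 5 to 45 in ndLN Tconv, and 145 to 300, 342 to 557, 539 to 966 and 502 to 913 between Treg and Tconv. The adjusted p ran from 9.21e-06 to 0.0264 for Rsrp1, 0.000174 to 0.154 for Dnaja1, 1.31e-23 to 0.154 for Hspa1b, 0.000174 to 0.191 for Junb, 1.04e-07 to 0.327 for Dusp1 and 0.0229 to 0.350 for Cirbp. Where no cause is given below, the cause was not tested.

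With no gene filter beyond 1 UMI, which adds genes to the test, the counts were 13 in islet Treg, 44 in ndLN Treg (7 of 7 shared), 13 for the difference of the differences (3 of 3), 40 in islet Tconv (1 of 1) and 45 in ndLN Tconv (9 of 9). The mean of per-cell CPM gave 11 in ndLN Treg (7 shared) and 7 for the difference of the differences (3 shared). Leaving out cycling cells gave 3 (3 shared) and 1 (1 shared). DESeq2 gave 14 in ndLN Treg (5 shared) and 18 in ndLN Tconv (9 shared). Without mice 1 and 12, with fewer samples, counts were 1 in islet Treg, 3 in ndLN Treg (2 shared), 1 for the difference, 0 in islet Tconv and 5 in ndLN Tconv (5 shared). Cells with a Foxp3 UMI in any T cell cluster gave 2 in ndLN Treg (2 shared), 373 in the wild type tissue comparison (326 shared), 1 for the difference, 0 in islet Tconv, 16 in ndLN Tconv (8 shared) and 145 in wild type islet Treg against Tconv (96 shared). A hashtag ratio of 10 gave 0 in islet Tconv, 14 in ndLN Tconv (9 shared) and 0 clonotypes shared between genotypes in islet Tconv. The mouse as a block, run for the Treg tissue comparisons and the difference only, gave 8 for the difference (3 shared). It kept the counts of both tissue comparisons within a factor of 1.5. Treg with and Tconv without a Foxp3 UMI gave 4 in islet Tconv (0 shared), and the interferon cluster as Tconv gave 16 in ndLN Tconv (9 shared).

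Nrp1 RNA between the tissues of wild type mice passed the threshold with the mean of per-cell CPM (0.97, edgeR adjusted p = 0.0135), without cycling cells (0.76, 0.0257) and with libraries of at least 10 cells (0.70, 0.0320). The thinned share of Treg with Nrp1 differed by 18.5 points in the islets (exact p = 0.0108) and 9.26 in the ndLN (exact p = 0.00216). The surface tag ratio between genotypes in the islets was 1.31 as a ratio to isotype (exact p = 0.130) and 3.57 as excess per hashtag (exact p = 0.156). Between wild type tissues it was 0.482 in libraries of at least 10 cells (exact p = 0.0625, the smallest possible with 5 pairs) and 0.479 as excess per hashtag (exact p = 0.125). Between Nrp1 allele tissues it passed with a Foxp3 UMI in any T cell cluster (0.420, exact p = 0.03125) and as a ratio to isotype (0.443, exact p = 0.03125).

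Treg-like shares reversed at resolution 1.5, to -1.71 points between genotypes in the ndLN and -4.45 between wild type tissues, and at 0.6 the Nrp1 allele tissue difference was -5.59 (exact p = 0.0625). Sema4a in islet Tconv gave -0.237 without mice 1 and 12 and -0.0787 at resolution 0.6. Nrp1 between wild type islet Treg and Tconv gave -0.0106 with the strict cell filter, -0.169 at ratio 10, -0.0733 with a Foxp3 UMI, -0.0936 in any T cell cluster, -0.144 at resolution 0.6 and -0.0167 at 1.5. The heat-shock list in islet Treg gave 0.0292 in any T cell cluster, and the ratio of heat-shock UMIs between genotypes in islet Tconv was 0.920 at hashtag ratio 10.

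Genes under the filter of a setting gave no value there. These were Rtp4 in ndLN Treg in 5 settings, Sema4a in Tconv in 5, Ccl4 in 4 (hashtag ratio 10, Foxp3 UMI, any T cell cluster, without mice 1 and 12), Nrp1 in Tconv at 100 CPM, and at 100 CPM the tissue genes Il10, Cdkn1a, Capn3, Ntn4, Rcn1, Atp1b1, Treml2, Eno1b, Rassf2 and Ifng. Of these Atp1b1, Capn3, Eno1b, Ifng, Rassf2 and Rcn1 were also under the filter when Treg were cells with a Foxp3 UMI. Capn3, Rcn1 and Eno1b were under it in any T cell cluster too, and Ifng and Eno1b at hashtag ratio 10. Eno1b was further under it with the strict cell filter and at resolution 1.5. Nrp1 in islet Treg rests on 120 and 78 UMIs.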

Other observations

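The measures here were chosen after the results were seen, apart from the Rosa26 test. Second hashtag counts on Treg had their own pattern. Wild type islet Treg carried 210 ± 73.3 (SD, n = 6), Nrp1 allele islet Treg 487 ± 163 (SD, n = 6; exact two-sided p = 0.00433), and ndLN Treg 717 ± 179 and 688 ± 161 (exact p = 0.775), a ratio of islet to ndLN of 0.293 and 0.707. In the S100a4, Itgae and Ccr6 cluster (96 islet and 121 ndLN cells) surface Nrp1 was 10.0 ± 1.30 and 10.4 ± 0.548 (SD, n = 5) in wild type and Nrp1 allele islets (exact p = 0.589) and 29.2 ± 6.74 and 47.9 ± 13.9 in the ndLN (exact p = 0.00216).

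A hypothesis written before its test was run was that DNA of another strain around the targeted Rosa26 locus might alter nearby genes. Within 10 Mb of the locus (6:113067428-113077244), 33 genes gave 11 of 122 tests with an unadjusted p under 0.05 (9.02%), against 6.61% of 17576 tests elsewhere, a ratio of 1.36 (95% interval 0.694 to 2.35). No gene there was called by edgeR after adjustment (0), 1 gene had such a p in 2 or more comparisons, and the interval leaves the question open.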
